A study of Mus musculus with 6 samples.

How the data were processed

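Gene expression was measured on microarrays in quadriceps muscle of 6 utrn+/-;mdx mice on the C57BL/10 background, 1 array per mouse. These mice lack dystrophin and carry 1 functional copy of the gene for utrophin, a dystrophin-related protein, and are a model of Duchenne muscular dystrophy. Per the labels' protocols, 3 mice were given 10 mg/kg per day lisinopril, an angiotensin-converting enzyme inhibitor, and 37.5 mg/kg per day spironolactone, a mineralocorticoid receptor antagonist, in drinking water from 4 to 20 weeks of age, and 3 mice had untreated water. Each group held 2 male mice and 1 female mouse. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase, cleaned on a column, amplified linearly from 100 ng and labelled with biotin. The labels number the mice as biological replicates, and groups were taken from the sample titles.

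The deposited value table held 45101 probe sets on the log2 scale, between 2.58 and 15.1 for the probe sets that are not controls. The submitters' processing notes name RMA (robust multi-array average), Affymetrix Expression Console and Transcriptome Analysis Console, with no role or order. RMA as usually run corrects background, quantile-normalizes arrays and summarizes the probes of a set on the log2 scale; the settings used are not given in the sources used here. After such a normalization a shift shared by most genes cannot be seen, and values near the floor are compressed, so that differences of dim genes are understated. The array annotation version and any genome build are not given in the sources used here. No scanner intensities were used, so that background correction could not be varied, and no detection calls were used.

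A second table, also deposited by the authors, held 60 probe sets with gene titles and symbols, the same log2 values, and the authors' comparison of treated with control mice. Its log2 values differed from those of the full table by at most 0.00033. Per the file headers, this table gives a parametric p-value, a false discovery rate (an adjusted p-value), a permutation p-value, the geometric mean intensity of each class and the ratio of treated over control as a linear fold change. The stated criterion of the series was a fold change of at least 2.

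Gene names came only from this second table, because neither the value table nor the reference table used here pairs probe sets with genes. Of its 60 probe sets, 54 carried 1 gene symbol (50 distinct symbols), 1 carried several symbols and 5 carried none. The Entrez identifiers of 50 of the 54 matched a RefSeq gene table of assembly GRCm38.p6, which was used for symbols only. It gave a newer symbol for 2 of them, Nmrk2 for Itgb1bp3 and Rsrp1 for D4Wsu53e. All other probe sets are given by identifier or as counts. Further probe sets of a named gene that missed the authors' selection would be among these and cannot be told, so agreement between a gene's probe sets is not shown.

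The 64 control probe sets were left out, and the remaining 45037 were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values, treated minus untreated, two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The main design had no covariate, because the series states a single pairwise comparison. Fold changes are differences of group mean log2 values, errors are standard deviations between mice or moderated standard errors, and the number of arrays limits the precision. Counts at a 2-fold difference follow the criterion stated for the series. In simulated data for the treatment comparison, drawn from the means and residual spread of the 45037 probe sets with 200 changed, the fit recovered 68.5% of the changes at 2-fold, 95.5% at 4-fold and 99.0% at 8-fold, with 4, 17 and 6 false calls. The simulated probe sets varied independently of each other, and the changed ones were drawn at random. The rates therefore do not hold for noisier genes. Myl2, for 1, had an SD of 3.37 in untreated mice, against a median of 0.147 over all probe sets.

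The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. There were 35 lists of pathway genes and cell type markers. A list was tested with camera at a preset correlation of 0.01 where at least 3 of its members were named, each gene by its brightest named probe set. Because all named genes were selected by the authors from these samples, only 2 lists could be tested, within 50 genes, and the test compares a list with other selected genes. The named genes are, in each direction, up to 12 genes with the largest fold change among those with non-overlapping groups, filled from genes at unadjusted p under 0.05 because fewer than 6 passed the adjusted threshold, plus up to 4 members of a called list, up to 2 of the others, and the 3 largest fold changes per direction in the authors' table. Predicted genes were left out of the first part, and only 10 genes higher in treated mice met it. The rule also named the genes of the drug targets and of the mouse model (Nr3c2, Nr3c1, Ace, Agt, Agtr1a, Utrn and Dmd). None of these is among the named probe sets, so they are not analysed here, nor are the Y-linked genes and Xist that were planned for the check of sex labels. Genes named outside the rule are said to be so. Of the genes that met the rule, 1 is not reported here.

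Alternatives were a filter that left out the dimmest 40% of probe sets, median centring, a further quantile normalization, a trended robust variance, sex as a term, the replicate number as a block, male mice alone, array weights, an ordinary analysis of variance, a 1.5-fold threshold, each array left out in turn, and for lists an estimated correlation, the mean of a gene's probe sets, and fry. The 3'-to-5' signal ratio of 4 spike controls was added as a term after the control probe sets had been seen, as were all alternatives for the count at an unadjusted p. No 2 arrays shared a value at more than 0.226% of probe sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.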

Results

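Transcript levels were compared in quadriceps of 3 utrn+/-;mdx mice given spironolactone plus lisinopril and 3 untreated utrn+/-;mdx mice, all dissected at 20 weeks of age. The comparison asks how combined mineralocorticoid receptor antagonism and angiotensin-converting enzyme inhibition alters gene expression in dystrophic limb muscle. The 6 arrays had median log2 values between 6.07 and 6.13 and correlated with one another at 0.974 to 0.995 across 45037 probe sets. The array of untreated mouse 3, the only untreated female, had the lowest mean correlation with the other arrays, 0.983. The rest had 0.988 to 0.992.

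All 5 named genes of the 12-gene slow-fibre list had lower means in treated mice. All 4 named genes of the 16-gene adipocyte list had higher means, but no probe set passed the adjusted threshold. The other members of both lists are outside the authors' selection, so their direction is not known here. Myl2, the slow and cardiac regulatory myosin light chain, was 15.1-fold lower in treated mice, and Arrdc2, an arrestin domain-containing gene, was 4.26-fold higher. The difference of Myl2 was 6.03-fold without untreated mouse 3 and 56.3-fold without untreated mouse 1, and that of Arrdc2 was 2.66-fold without untreated mouse 3 and 6.36-fold without untreated mouse 2. With the 3'-to-5' signal ratio of spike controls, RNAs added to gauge labelling, as a term, chosen after seeing the data, Myl2 was 2.09-fold lower and Arrdc2 3.92-fold higher, and with array weights Myl2 was 8.01-fold lower. The fold moved by over 1.5 times for 13 of the 54 single-gene probe sets when 1 mouse was left out, for 23 with the spike term (17 lower and 6 higher in treated mice) and for 6 with array weights. The lowest limma adjusted p over all probe sets was 0.603, so that limma called 0 probe sets, and an ordinary analysis of variance per probe set called 1, which has no gene name in the files used here. At an unadjusted p under 0.05 there were 3443 probe sets, where 2252 would be expected with no effect. Of these, 1982 were higher and 1461 lower in treated mice, a split that turned to 1194 higher and 2201 lower after median centring of the arrays. A difference of 2-fold or more was found for 132 probe sets, 47 higher and 85 lower, of which 69 also had an unadjusted p under 0.05. With the spike term there were 64 at 2-fold, and the balance turned to 39 higher and 25 lower. The groups did not overlap for 36 of the 132 (27.3%), against 14.3% of all probe sets and 10% by chance for 3 against 3 arrays. The 132 were picked for their mean difference on these same arrays, which raises their share. It is therefore no evidence of a treatment effect. Leaving out single mice moved these counts, with 0 limma calls each time: the 132 became 522 without untreated mouse 1 and 278 without treated mouse 2, and the 69 became 429 and 111 without these mice and 42 without treated mouse 1. The 3443 became 7456 without untreated mouse 1, 1711 without untreated mouse 2, 1434 without treated mouse 1 and 1651 without treated mouse 3.

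**Figure D1:**
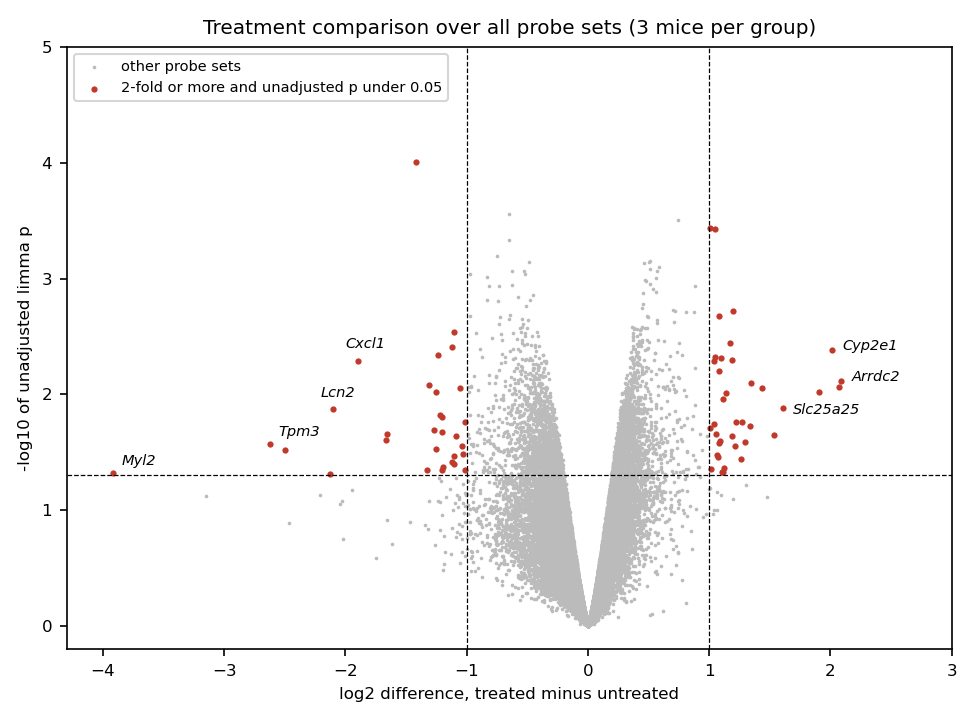
Log2 difference between treated and untreated mice (x axis) against the -log10 of the unadjusted limma p (y axis) for 45037 probe sets, with dashed lines at 2-fold and at an unadjusted p of 0.05. The 69 red points pass both lines, and none of them passes after adjustment.

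The authors' deposited table lists 60 of these 69 probe sets, and these are the ones with gene names. The other 9 had geometric group means of at most 94.8 on the linear scale in either group, whereas the higher group mean of the listed probe sets was 117.6 or more. The genes furthest below the untreated level in the authors' deposited table were Myl2 (15.1-fold lower), Tpm3 (6.14-fold lower on 1 of its probe sets) and Lcn2 (4.29-fold lower), with a probe set shared by Myh6 and Myh7 at 4.37-fold lower. Those furthest above it in the authors' deposited table were Arrdc2 (4.26-fold higher), 6030422H21Rik (4.20-fold higher) and Cyp2e1 (4.04-fold higher). The false discovery rate given in the authors' deposited table was 0.601 for each of the 60, and the limma adjusted p was 0.603 for each. The 60 comprise 28 probe sets lower and 32 higher in treated mice, and the 2 groups did not overlap for 30 of them. Adjusted over the list alone all 60 passed, with a lowest limma adjusted p of 0.0112, which is not independent evidence: the authors chose these probe sets on the same samples, and a set whose unadjusted p values all lie under 0.05 must pass.

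Slow-fibre genes formed the largest named group. All 5 named members of the 12-gene slow-fibre list had lower means in treated mice: Myl2, Tpm3, Tnnt1, Tnnc1 and Myl3, which encode myosin light chains, tropomyosin and the slow troponin T and C subunits. Myl2 averaged 10.6 ± 3.37 on the log2 scale (SD, n = 3) in untreated mice and 6.67 ± 1.93 (SD, n = 3) in treated mice. Tpm3 averaged 9.87 ± 2.03 untreated and 7.25 ± 0.915 treated, and its other named probe set gave a 5.64-fold difference. Tnnt1 was 3.15-fold lower (log2 difference -1.65, SE 0.57), Myl3 was 2.51-fold lower (-1.33, SE 0.55) and Tnnc1 was 2.42-fold lower (-1.27, SE 0.43). Without untreated mouse 3 the differences were 3.35-fold for Tpm3, 2.06-fold for Tnnt1, 1.90-fold for Myl3 and 1.70-fold for Tnnc1, and without untreated mouse 1 they were 13.3-fold, 4.62-fold, 4.05-fold and 3.13-fold. With the spike term they were smaller still, at 1.82-fold for Tpm3, 1.72-fold for Tnnt1, 1.36-fold for Myl3 and 1.495-fold for Tnnc1. The groups did not overlap for Tnnc1, and for the other 4 genes untreated mouse 1 lay within the treated range. Over all probe sets 0 of the 5 passed, and adjusted over the list alone 5 of 5 did (limma, highest adjusted p 0.0481), which the authors' selection fixes, because no listed probe set had an unadjusted limma p above 0.0485. The probe set shared by Myh6 and Myh7, the cardiac and slow myosin heavy chains, averaged 9.48 ± 2.04 untreated and 7.35 ± 0.543 treated. The Myl3 probe set carries the x_at suffix of sets whose probes may match several transcripts.

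The mean over the 5 slow-fibre genes was 10.1 ± 1.70 in untreated mice and 7.97 ± 0.836 in treated mice. An exact two-sided permutation test over mice gave p = 0.2, where the smallest value that 3 against 3 mice allow is 0.1. Single mice had means of 8.28, 10.5 and 11.6 in the untreated group and 7.34, 7.65 and 8.92 in the treated group. The highest mean in each group was that of its only female, mouse 3. Leaving out untreated mouse 3 therefore also leaves sex unbalanced between the groups. Within the authors' selection, camera called the list lower (limma camera adjusted p = 0.0007 over the 2 lists tested). The call was lost with an estimated correlation (limma adjusted p = 0.263) and with the 3'-to-5' signal ratio of the spike controls as a term (adjusted p = 0.0629). By fry, which asks whether the genes move on balance 1 way and compares them with no other genes, the list had an adjusted p = 0.119. In the same selection 18 of the other 45 genes were lower, against 5 of 5 here (Fisher's exact test across genes, which are not independent, two-sided p = 0.0159). The authors chose these genes on these samples, so none of these tests is independent evidence of direction. The 3'-to-5' signal ratio of the poly-A spike controls correlated with the slow-fibre mean across the 6 mice at r = 0.926 (exact permutation p = 0.0125, adjusted 0.0188).

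**Figure D2:**
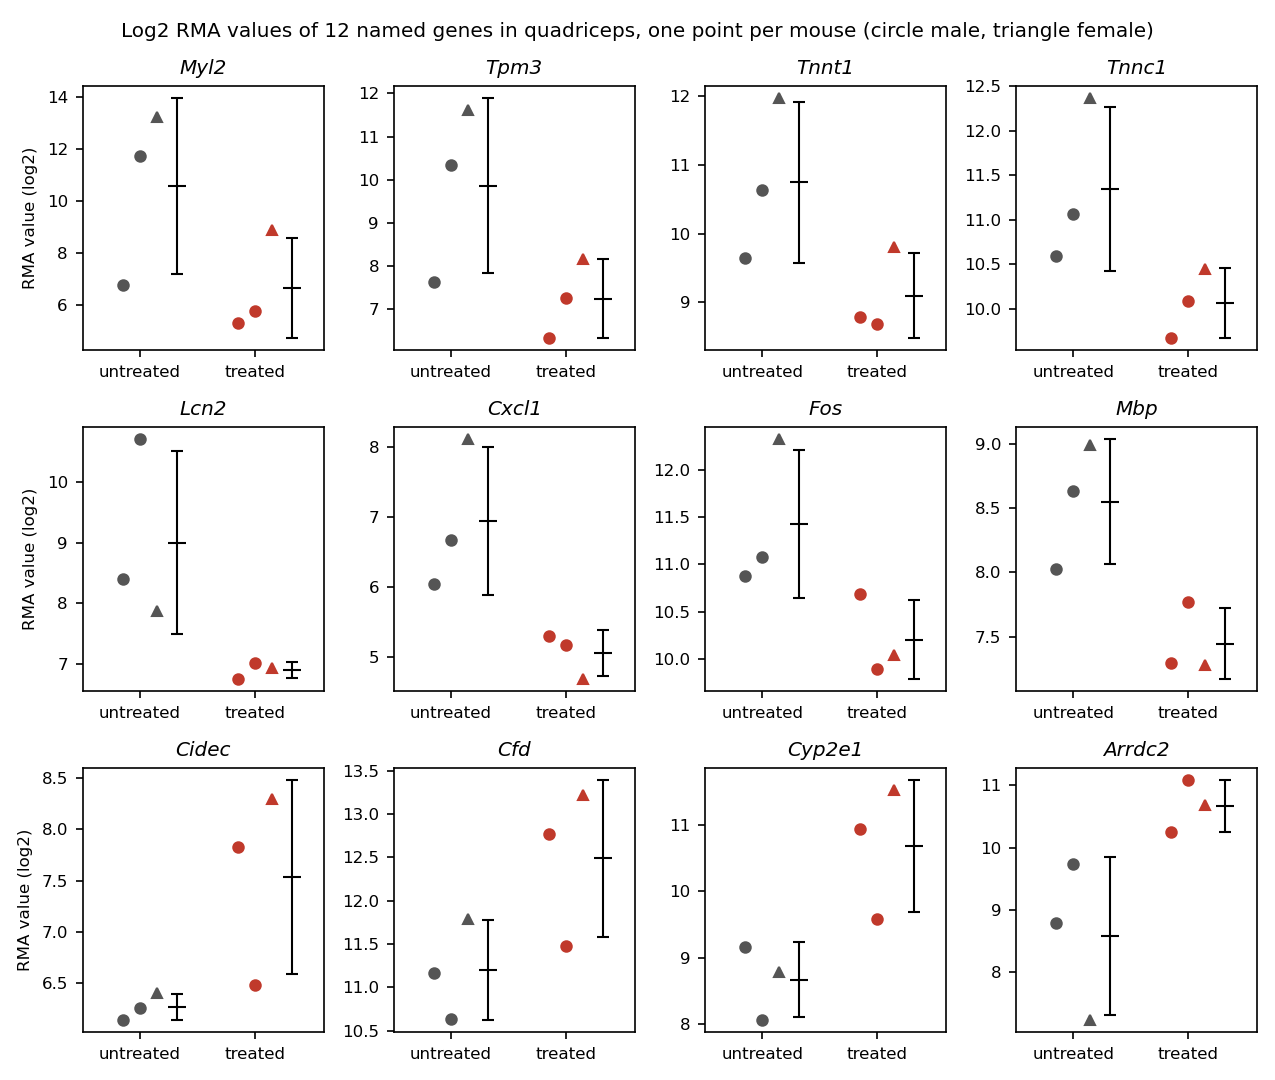
Log2 RMA values of 12 named genes (y axes) in untreated (grey) and treated (red) mice, with circles for males, triangles for females, and a bar for the mean ± SD of 3 mice. Myl2 averaged 10.6 untreated and 6.67 treated with untreated mouse 1 within the treated range, whereas Lcn2, Cxcl1 and Cyp2e1 do not overlap between groups.

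Outside the slow-fibre list, 10 further genes named by the rule had lower means in treated mice. Lcn2, which encodes the secreted iron-siderophore binding protein lipocalin 2 and was on the corticosteroid-responsive list, averaged 9.0 ± 1.51 untreated and 6.90 ± 0.139 treated (4.29-fold lower). Cxcl1, a neutrophil-attracting chemokine, averaged 6.94 ± 1.06 untreated and 5.05 ± 0.330 treated (3.72-fold lower). Without untreated mouse 2 the difference of Lcn2 was 2.37-fold, and without untreated mouse 3 that of Cxcl1 was 2.47-fold; with array weights Lcn2 was 6.98-fold lower. Fos, an immediate early transcription factor, was 2.33-fold lower (log2 difference -1.22, SE 0.387), and Sik1, a salt-inducible kinase, was 2.30-fold lower (-1.20, SE 0.385). Mbp, which encodes myelin basic protein and was the only named Schwann cell marker, was 2.15-fold lower (-1.10, SE 0.252). Npr3, the natriuretic peptide clearance receptor, was 2.38-fold lower and Lmod2, a leiomodin that regulates thin filament length, was 2.35-fold lower. Mid1ip1, a lipogenic regulator, was 2.48-fold lower, Inhbb, an inhibin and activin subunit, was 2.17-fold lower, and Ahr, the aryl hydrocarbon receptor, was 2.08-fold lower. With the spike term Npr3 was 1.56-fold lower and Sik1 was 3.50-fold lower. The values of untreated and treated mice did not overlap for the genes of this paragraph, and none passed the adjusted threshold.

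All 4 named members of the 16-gene adipocyte list had higher means in treated mice: Cfd (adipsin) by 2.45-fold, Cidec, a lipid droplet protein, by 2.41-fold, Retn (resistin) by 2.16-fold and Pck1, the cytosolic phosphoenolpyruvate carboxykinase, by 2.15-fold. Cfd averaged 11.2 ± 0.577 untreated and 12.5 ± 0.904 treated, and Cidec averaged 6.27 ± 0.131 untreated and 7.54 ± 0.948 treated. Cidec did not overlap between groups, while Cfd, Retn and Pck1 did. Retn and Pck1 were named after their values had been seen, to complete the list. The list mean was 7.90 ± 0.332 untreated and 9.09 ± 0.930 treated (exact two-sided permutation p = 0.2). Pck1 was 1.71-fold higher without treated mouse 3 and 3.27-fold higher without treated mouse 2, and with array weights Cfd was 3.73-fold and Retn 3.52-fold higher. Treated mouse 2 had a list mean of 8.05, against 9.40 and 9.82 in the other treated mice and 7.54 to 8.20 in untreated mice. Camera did not call the list within the authors' selection (limma camera adjusted p = 0.0958, and adjusted p = 0.401 with an estimated correlation). Adjusted over the list alone, 4 of 4 had a limma adjusted p of 0.0469, which the authors' selection on these samples likewise fixes, and over all probe sets 0 of 4 passed. It was called when treated mouse 2 was left out (adjusted p = 0.0159) and when untreated mouse 3 was left out (adjusted p = 0.0342).

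Among the other genes with higher means in treated mice, Cyp2e1, a cytochrome P450 found in liver and fat, averaged 8.67 ± 0.563 untreated and 10.7 ± 0.991 treated (4.04-fold higher, and 6.34-fold with array weights). Ces1d, a carboxylesterase with triglyceride hydrolase activity, was 2.33-fold higher (log2 difference 1.22, SE 0.401). Thrsp, a thyroid hormone responsive lipogenic gene, was 2.12-fold and 2.14-fold higher on its 2 named probe sets. Gpt2, the mitochondrial alanine aminotransferase, was 2.06-fold higher. Ppp1r3c, a glycogen-targeting subunit of protein phosphatase 1, was 2.07-fold higher, and Gpd1, the cytosolic glycerol-3-phosphate dehydrogenase and the only named gene of the glycolysis list, was 2.16-fold higher. The groups overlapped for Gpd1 but not for Cyp2e1, Ces1d, Thrsp, Gpt2 or Ppp1r3c.

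Of the remaining named genes with higher means, Arrdc2 averaged 8.58 ± 1.27 untreated and 10.7 ± 0.417 treated, and Slc25a25, a mitochondrial ATP-magnesium and phosphate carrier, averaged 8.99 ± 1.12 untreated and 10.6 ± 0.238 treated (3.04-fold higher, 1.96-fold without untreated mouse 3 and 1.90-fold with the spike term). Itgb1bp3, now named Nmrk2, a nicotinamide riboside kinase of muscle, was 2.12-fold higher (log2 difference 1.08, SE 0.234). Mybph, the myosin binding protein H, was 2.06-fold higher (1.04, SE 0.343). Jph2, a junctophilin of the triad junction and the only named gene of the excitation-contraction list, was 2.01-fold higher, with overlapping groups. None of these genes passed the adjusted threshold.

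Of the 35 lists fixed in advance, 2 had at least 3 named members, 6 had a single named member (Lcn2, Cxcl1, Fos, Mbp, Gpd1 and Jph2, described above) and 27 had none. The lists with none include the renin-angiotensin system, fibrillar matrix, TGF-beta signalling, macrophage and regenerating fibre lists. None of their members was named. Names were limited to probe sets at 2-fold or more with an unadjusted p under 0.05 and a higher group mean of 117.6 or more. Smaller, dimmer or less certain differences in these lists cannot be seen here.

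The spike and housekeeping controls differed among the arrays. The mean 3'-minus-5' log2 signal of 4 poly-A spikes was 1.63 ± 0.168 on untreated and 1.46 ± 0.121 on treated arrays (exact two-sided permutation p = 0.3). The highest values were those of untreated mice 2 and 3, 1.69 and 1.76, and treated mouse 1 had the lowest, 1.32. The same difference for Gapdh, an endogenous transcript, was 0.444 ± 0.199 untreated and 0.197 ± 0.0395 treated (exact two-sided permutation p = 0.2). Across the 6 arrays the spike value correlated with the slow-fibre list mean (Pearson r = 0.926, exact permutation p = 0.0125, adjusted 0.0188; Spearman rho = 0.943, exact permutation p = 0.0167, adjusted 0.025). Without untreated mouse 3 and treated mouse 1, the arrays farthest from the median, r was 0.835. It correlated with the first principal component, which held 54.8% of the variance, at r = 0.959 (exact permutation p = 0.00278, adjusted 0.00834; rho = 0.943, exact permutation p = 0.0167, adjusted 0.025), and at r = 0.962 without those 2 arrays. Its correlation with the adipocyte list mean was r = -0.501 (exact permutation p = 0.285, adjusted 0.285; rho = -0.143, exact permutation p = 0.803, adjusted 0.803), and r = -0.302 without those 2 arrays. These were the 3 relations computed, and 3 arrays per group are too few to repeat them within a group.

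**Figure D3:**
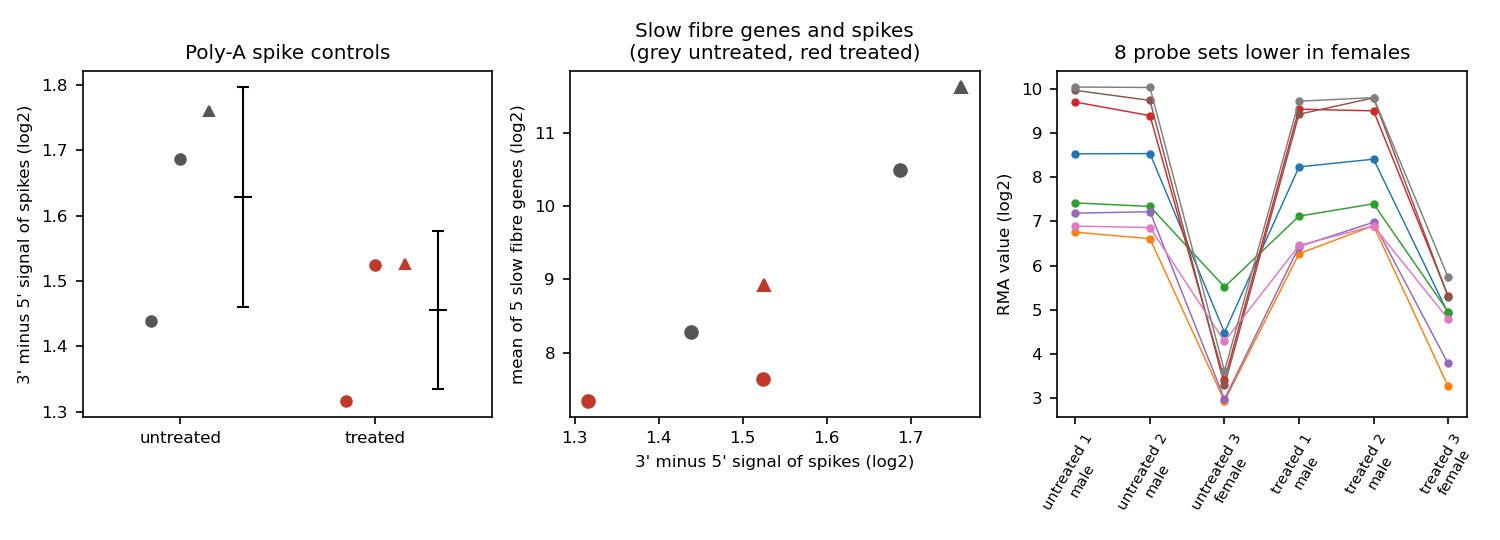
Left, 3'-minus-5' log2 signal of the poly-A spikes per mouse with mean ± SD; middle, mean log2 value of 5 slow-fibre genes against it; right, log2 values on each array of 8 probe sets chosen for being lower in females, with 1 line per probe set. Untreated mice 2 and 3 have the highest spike values, 1.69 and 1.76.

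A female-minus-male contrast by the labels, with treatment as a term, called 4 probe sets, all lower in the 2 females, with a lowest limma adjusted p of 0.00424 for a probe set with a log2 difference of -3.72 (SE 0.162). The 4 have no gene name in the files used here, and because the labels selected them they are no independent check of the labels. The treatment-by-sex interaction called 0 probe sets (lowest limma adjusted p = 0.409), with 2325 at an unadjusted p under 0.05. It rests on 1 female per group, assumed to vary like the males.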

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

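The tests of the share of male signal and of the co-movement of list genes, the spike ratio as a term, and the adjustment of the sex interaction over the 60 named probe sets were chosen after the data had been seen.

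For 4 named genes the limma interaction of treatment with sex had an adjusted p of 0.032 over the 60 named probe sets, which the authors chose on these samples, and of 0.539 to 0.575 over all probe sets. A sex difference is not shown by this, since each group holds 1 female and the untreated female is the mouse with the lowest mean array correlation (0.983) and the highest spike ratio (1.76). For Cxcl1 the female difference exceeded the male one by -2.32 on the log2 scale: -3.44 between the 2 females and -1.12 between the males. For Inhbb it was -1.83, from -2.34 in females and -0.51 in males. For Thrsp it was 1.48 on 1 of its 2 probe sets, from 2.07 in females and 0.59 in males (adjusted p = 0.0624 on the other), and for Slc25a25 it was 1.502, from 2.61 in females and 1.10 in males. In all 4 the direction was the same in males and females.

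The treated female carried more signal than the untreated female on 7 of 8 probe sets that were lower in females at a limma adjusted p under 0.1. The differences ran from -0.56 to 2.13 on the log2 scale, with a median of 0.66; 5 of the 8 lay under 4 on the log2 scale in the untreated female, near the lowest value of 2.58, where no detection was tested and log differences depend on the background. A general rise of dim signals on that array is argued against: 18120 other probe sets as dim in the untreated female were higher by 0.084 in the median, and 0.866% of them by as much as 0.66. The excess equalled 3.77% of the male level in the median (middle 50% from 2.39% to 4.56%, range -12.9% to 9.2%), so a small admixture of male RNA in that sample may be a candidate, as a hypothesis that values this near the floor leave open. An effect of treatment in females stays open, with 1 female per group; in males the 8 probe sets were lower by 0.206 in treated mice, in the median.

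Most probe sets at 2-fold were lower in treated mice (85 of 132), but with the spike ratio as a term 39 were higher and 25 lower. Untreated mouse 3 alone is argued against as the source, since 62 were 2-fold lower and 32 higher without it. Labelling that favours 3' ends may account for part: with that term, the median difference of the 132 shrank from 1.17 to 0.497. That term correlates at -0.586 with treatment over the 6 arrays, so a treatment effect that runs with it would shrink too, and stays open. It also correlates at 0.959 with the first principal component, so any other difference among the mice along that component would shrink as well. Another split of the mice, untreated 1 with treated 1 and 3 against the others, gave 360 probe sets at 2-fold, above the real 132. It gave 6431 at unadjusted p under 0.05, above the real 3443. This split had the highest counts of all and keeps most mice on their treatment side. It therefore cannot tell a structure other than treatment from a treatment effect with atypical mice.

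The slow-fibre and adipocyte genes each moved together between mice of 1 group. The median pairwise correlation of deviations from the group means was 0.935 for the 5 slow-fibre genes, but 0.691 for the 18 other genes lower in treated mice, so the co-movement does not single out slow-fibre tissue, and a difference in its share stays open. It was 0.846 for the 4 adipocyte genes and 0.264 for the 23 other genes higher in treated mice. A share of fat tissue that varied between the dissected muscles is a candidate. Sex was not removed from these deviations. The female had the highest adipocyte mean of her group (8.20 untreated, 9.82 treated) and the highest slow-fibre mean (11.6 untreated, 8.92 treated). A sex difference could give such co-movement and stays open. With the spike ratio as a term the median slow-fibre difference shrank from -1.65 to -0.784, so labelling bias may contribute there. The spike ratio also correlated with the first principal component (r = 0.959) and with treatment (r = -0.586), so this shrinkage cannot single out labelling. The adipocyte difference was 1.16 with the term and 1.19 without, which argues against labelling bias for the adipocyte genes. Whether a difference in tissue share came from dissection, from sex or from treatment stays untested.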

How the results depend on the processing

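The spike term and all alternatives for the count at unadjusted p were chosen after seeing the data. No probe set passed the adjusted threshold under any alternative except the ordinary analysis of variance, which called 1 without a gene name, higher in treated mice by 0.36 on the log2 scale with an adjusted p of 0.0436 and a limma adjusted p of 0.603. The lowest limma adjusted p otherwise ranged from 0.0581 without untreated mouse 1 to 0.972 with the spike ratio as a term. None of the 864 values of the 54 single-gene probe sets under alternatives reversed. Few could, since the authors chose these probe sets for a large difference on the same samples. The dim filter, trended variance, sex term, replicate block and analysis of variance also leave the difference itself unchanged. With the spike ratio as a term 64 probe sets were 2-fold different (39 higher, 25 lower), 39 of them with an unadjusted p under 0.05, there were 1507 at an unadjusted p, and 0 lists were called (slow-fibre limma adjusted p = 0.0629). At 1.5-fold there were 907 probe sets (227 higher, 680 lower). The count at an unadjusted p was 1901 without the dimmest probe sets, 1353 in males alone and 7986 with array weights. Whether the replicate numbers pair the mice is not settled. The deviations of same-numbered mice from their group means correlated at 0.517, -0.0824 and 0.183, against a set minimum of 0.1 for pairing. Mouse 3 is the female in both groups, so the numbers also carry sex. The replicate block gave 112 probe sets at 2-fold and an unadjusted p under 0.05 and 5124 at an unadjusted p, with 0 calls; 1 of the 3 untreated mice correlated best with the treated mouse of its own number. The sex interaction had 0 limma calls in its 4 alternatives (lowest adjusted p from 0.19 to 0.57). The estimated correlation and fry each called 0 lists. Leaving out 1 mouse gave 0 calls each time, 94 to 522 probe sets at 2-fold, 42 to 429 of these with an unadjusted p under 0.05, 1434 to 7456 at an unadjusted p, and 1 to 2 lists called. The highest counts of probe sets came without untreated mouse 1, and 2 lists were called without untreated mouse 3 and without treated mouse 2; without untreated mouse 3, 25 of the 54 single-gene probe sets stayed at 2-fold, 23 in males alone and 19 with the spike ratio as a term. The cause of these changes was not tested.

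As to other splits of the 6 arrays, there are 10, too few for a share under 0.05. Counting the real one, 10 gave as many adjusted calls (0, highest other 0), 3 as many at an unadjusted p (3443, highest other 6431), 4 as many at 2-fold (132, highest other 360) and 8 as many lists (1, highest other 2). Signal near the floor of the arrays limits the dim probe sets.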

Other observations

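Every one of the 26 single-gene probe sets lower in treated mice varied more between untreated than between treated mice, whereas 14 of the 28 higher ones did. Over all probe sets, 60.6% varied more in untreated mice, with a median SD of 0.147 untreated and 0.121 treated. With 1 mouse left out an SD rests on 2 mice, so it is compared here only with other SDs of 2 mice. The median SD of the untreated mice was 0.118 without untreated mouse 1, 0.137 without untreated mouse 2 and 0.107 without untreated mouse 3. The treated mice with 1 left out gave 0.0821, 0.0975 and 0.118, so these ranges of the groups overlapped. Whether the gap rests on single mice cannot be told from this. Inhbb had an SD of 1.02 untreated and 0.109 treated, Lcn2 1.51 and 0.139, and Mid1ip1 0.832 and 0.111. The untreated SD was 0.405 for Inhbb without untreated mouse 3, 0.38 for Lcn2 without untreated mouse 2 and 0.459 for Mid1ip1 without untreated mouse 1. With either other untreated mouse left out it was 0.998 or 1.4 for Inhbb, 2.01 or 1.63 for Lcn2 and 1.17 or 0.708 for Mid1ip1. Leaving out the outermost of 3 values always lowers an SD, so this cannot show that single mice carried the spread. For genes picked by a lower mean in 1 group, high values in single untreated mice enter both the mean and the spread. Further genes of the authors' selection, named after their values had been seen, also differed by 2-fold or more. Prg4 (lubricin), a joint lubricant, was 3.18-fold lower in treated mice. Ankrd1, a stretch-responsive cardiac ankyrin repeat gene, was 2.16-fold and 2.05-fold lower on its 2 named probe sets. Itga5 was 2.06-fold lower and Serpina3m was 2.30-fold lower. Mbd2 was 3.75-fold higher, Kcng4, a potassium channel subunit, 2.40-fold, Cited4 2.32-fold, Tob1 2.29-fold, Cdo1, cysteine dioxygenase, 2.17-fold and Gadd45g 2.10-fold. With 1 mouse left out, the fold of Prg4 ran from 2.27 (without untreated mouse 3) to 5.34 (without untreated mouse 1), that of Serpina3m from 1.72 (without untreated mouse 2) to 3.57 (without untreated mouse 1) and that of Mbd2 from 2.88 (without untreated mouse 1) to 5.92 (without untreated mouse 2). With the spike ratio as a term, chosen after seeing the data, Prg4 was 1.51-fold, Serpina3m 1.45-fold, Ankrd1 1.35-fold and 1.31-fold, and Itga5 1.33-fold lower, and Kcng4 was 1.46-fold, Tob1 1.39-fold and Cited4 1.38-fold higher, while Cdo1 was 3.50-fold higher with array weights. The values of untreated and treated mice overlapped for each of these genes, and none passed the adjusted threshold.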
